A study of Rattus norvegicus with 6 samples.

How the data were processed

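The samples are livers of 3 control and 3 TPN rats, grouped by their titles. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made by standard Illumina methods. Per the submitters' processing notes, Bowtie 0.12.2 and Cufflinks were used with the rat genome build Rnor_6.0, in a role and order not given in the sources used here. The authors deposited 1 table of FPKM, a unit that divides fragments by transcript length and by the mapped total of the library, so that it holds no counts. Its columns were matched to samples by name. Ratios of values under 0.3 FPKM between samples were checked for steps of whole reads. At most 0.853% of them fell in 1 bin of width 0.01 (log2), so reads could not be recovered, depth is unknown, and no interval from counting error is given. The 10 most abundant features held 23.2% to 28.1% of a sample's FPKM. Strandedness and the treatment of reads shared by near-identical genes are not given in the sources used here. Positions in the genome were not used here.

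Features with a mean of at least 1 FPKM over the 6 samples were kept, and log2(FPKM + 1) was tested with limma 3.58.1 (statmod 1.5.0, R 4.3.3), with empirical Bayes moderation using a trend and robust settings, the group as the only term, 2-sided p and Benjamini-Hochberg adjustment at 0.05. A fold change on this scale understates the change of low genes. The labels name 3 rats per group. A test of ranks on 3 against 3 cannot give an exact p under 0.10, which is why the model across genes was used. Data were simulated for TPN against control with the means of these 11362 features. The same test found 29 of 100 genes changed by 1 on the log2 scale and 88 of 100 changed by 2. Among 121 called, 4 were unchanged. The changes were put only on genes with a mean log2(FPKM + 1) above 3. The spread was drawn from the prior of limma's fit, and genes varied independently. Real genes move together and several that passed lie lower, so these rates may not hold for them.

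Lists of genes, 39 with 710 entries, were fixed before the data were examined, and so were the tests, the rule for named genes and most alternatives. Symbols of the table matched 662 entries, older symbols from the RefSeq gene table of GRCr8 matched 7, and 41 had no match. Lists with at least 5 measured members, 32 in all, were tested with camera with a preset correlation of 0.01, and beside it with an estimated correlation, on ranks and with fry. Counts adjusted over the list alone correct only for the members of that list. The named genes were the 12 with the largest change in each direction among those past the threshold with a mean of at least 5 FPKM, a symbol and no overlap between groups, filled to 6 by unadjusted p, then up to 4 members of each list discussed, and 19 genes fixed in advance, of which 2 are not reported here. After the tests were run, the lists discussed were taken as those past the camera threshold. The lists were bile acid synthesis, bile acid and bilirubin transport, bile acid receptors, sterol efflux, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation, lipid droplets, gluconeogenesis, glycolysis, amino acid catabolism, the growth hormone axis, acute phase, cytokines, interferon, MHC class II, endoplasmic reticulum stress, oxidative stress, xenobiotic metabolism, cell cycle, p53 targets, sex-linked genes, the clock, glucocorticoid response, metals, respiratory chain, hepatocyte proteins, and markers of T and NK, B, Kupffer, neutrophil, stellate, cholangiocyte, endothelial, erythroid, pancreas, adipocyte, muscle and intestinal cells.

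Alternatives were pseudocounts of 0.1 and 0.01, no filter or a mean of at least 0.1 or 5 FPKM, median-ratio scaling, quantile normalisation, scaling to TPM (a fixed total per sample), moderation without trend or robust settings, sample weights (arrayWeights), the replicate number as a block, rows of the same symbol summed, and each rat left out in turn. Added after seeing the data were an acute-phase score or a clock score as a covariate, and control 2 and TPN 1 left out together. The acute-phase score is the mean log2(FPKM + 1) of the measured members of that list, and the clock score is the mean of Dbp, Tef, Hlf, Per1, Per2 and Per3 minus the mean of Arntl, Npas2 and Clock. A further covariate, the same clock score with Nr1d1 and Nr1d2 among the first genes, was added later. The check of group labels took lists, list members past the threshold over their list alone, and the 100 features with the smallest p, each from a fit without the rat. Folds in the text are ratios of mean FPKM. Figures were drawn with matplotlib 3.10.9.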

Results

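RNA-seq of liver was compared between 3 control rats given 0.9% saline and 3 rats given total parenteral nutrition (TPN, all nutrients infused into a vein) for 7 days. The animals were Sprague-Dawley rats, labelled as 4 weeks old, and the TPN rats carried the disease label parenteral nutrition-associated liver disease, which names liver injury that arises during such feeding. The question the labels set is which liver transcripts differ between the groups. The deposited table holds FPKM (fragments scaled to the length of the transcript and to the mapped total of the library) for 25926 features, of which 22050 have Ensembl identifiers and 3876 are named as new genes outside the annotation. The FPKM of a sample summed to between 509630.0 and 544670.0. Low values showed no steps of whole reads, so the depth of each library is unknown. Between 11129 and 11424 features reached 1 FPKM in a sample. Pearson correlations of log2(FPKM + 1) ran from 0.961 to 0.981 within the control group, from 0.942 to 0.968 within the TPN group and from 0.920 to 0.961 between the groups. The Y-linked genes Eif2s3y and Kdm5d were present in all 6 samples, with 20.3 ± 2.34 and 16.5 ± 3.66 FPKM (SD, n = 3) for Eif2s3y in control and TPN.

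In TPN liver, genes of cholesterol synthesis, erythroid genes and cell cycle genes fell, while the few genes that rose included Mthfd2, a mitochondrial enzyme of one-carbon metabolism. Of 11362 features with a mean of at least 1 FPKM, 28 passed limma's test at a Benjamini-Hochberg adjusted p under 0.05, of which 3 were higher and 25 lower in TPN. All 28 changed at least 2-fold on the log2(FPKM + 1) scale and showed no overlap between the values of the groups. Without regard to the test, 911 features were higher and 1033 lower in TPN without overlap, which is 17.1% against 10% by chance. At an unadjusted p under 0.05 there were 504 higher and 796 lower features, where 568 in all are expected by chance. That number varies widely where genes move together. Splits of the 6 rats that mixed the groups gave 107 to 1718 such features. The excess of lower features turned round without TPN 1 (802 higher and 687 lower) and with an acute-phase score as a covariate (630 higher and 547 lower), and the counts were 220 higher and 397 lower without control 1, 268 higher and 522 lower without control 3 and 390 higher and 1003 lower without TPN 3. The count of 28 depended on single libraries, falling to 3 without control 1, 6 without control 3, 1 without TPN 2 and 0 without TPN 3 (1393 at an unadjusted p under 0.05), and rising to 46 without control 2. It was also 0 by limma after median-ratio scaling or quantile normalisation, with 1573 and 1591 features at an unadjusted p under 0.05. Of these, 610 were higher and 963 lower after median-ratio scaling, and 764 higher and 827 lower after quantile normalisation.

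All 25 measured genes of the cholesterol synthesis list, which are targets of the transcription factor SREBP2, were lower in TPN liver, with a median log2 fold change of -1.35, and in 23 of them the values of the groups did not overlap. Tm7sf2, a sterol reductase, fell 10.9-fold, from 54.2 ± 5.62 to 4.99 ± 2.81 FPKM (SD, n = 3). Its log2 fold change was -3.30 (SE 0.31, limma adjusted p = 0.0166). Msmo1, the methylsterol monooxygenase, fell 5.85-fold, from 114 ± 51.04 to 19.5 ± 3.84 FPKM (log2 fold change -2.41, SE 0.33, limma adjusted p = 0.0422). Dhcr7, which makes cholesterol from 7-dehydrocholesterol, fell 4.36-fold, from 52.6 ± 7.32 to 12.1 ± 2.26 FPKM (log2 fold change -2.04, SE 0.19, limma adjusted p = 0.0166). Mvd, the mevalonate diphosphate decarboxylase, fell 3.55-fold, from 14.4 ± 3.16 to 4.05 ± 0.663 FPKM (log2 fold change -1.59, SE 0.19, limma adjusted p = 0.0391). These 4 passed over all genes tested, and all 25 passed when adjusted over the list alone. The list ranked lower than other genes (camera adjusted p = 2.23e-29, and adjusted p = 0.21 with an estimated correlation). Fry, which tests whether a list's genes move one way on balance, gave an adjusted p of 0.0308.

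**Figure D1:**
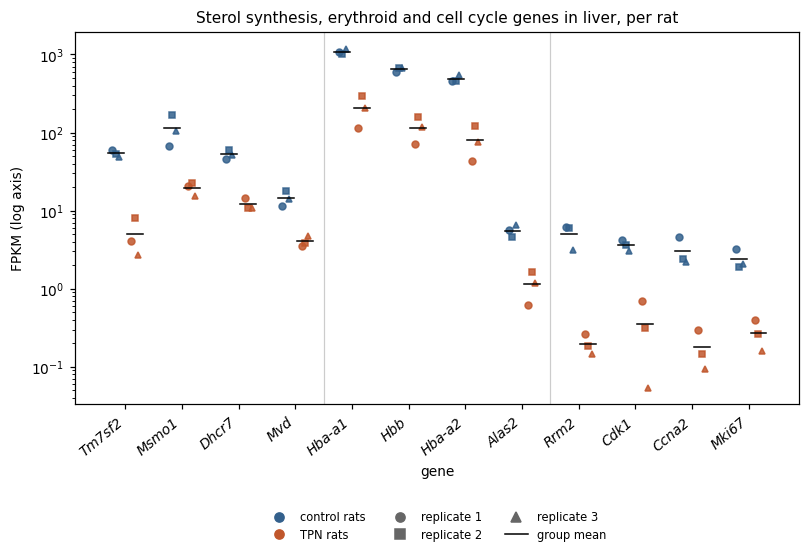
FPKM on a log axis of 4 cholesterol synthesis genes (left), 4 erythroid genes (middle) and 4 cell cycle genes (right) in the liver of 3 control and 3 TPN rats. Each point is 1 rat, its shape gives the replicate number and the horizontal lines are group means. In all 12 genes every TPN rat lies below every control rat.

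All 6 measured erythroid genes were lower in TPN liver, without overlap between the groups, with a median log2 fold change of -2.06. Hba-a1, an alpha globin, fell 5.24-fold, from 1083 ± 93.3 to 207 ± 90.8 FPKM (SD, n = 3; log2 fold change -2.48, SE 0.34, limma adjusted p = 0.0422). The values were 484 ± 55.5 FPKM in control and 80.4 ± 40.02 in TPN for Hba-a2 (limma adjusted p = 0.0418) and 648 ± 41.1 FPKM in control and 115 ± 42.5 in TPN for Hbb, a beta globin (limma adjusted p = 0.0353). Alas2, which starts heme synthesis in red cell precursors, fell from 5.56 ± 0.975 to 1.14 ± 0.498 FPKM (limma adjusted p = 0.0418). These 4 passed over all genes and all 6 passed adjusted over the list alone. Globin genes have near-identical copies that share reads, so the split of FPKM among them is uncertain. The list ranked lower (camera adjusted p = 5.02e-11, and adjusted p = 0.21 with an estimated correlation). Fry gave an adjusted p of 0.0308.

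Of 18 measured cell cycle genes 17 had negative log2 fold changes, with a median of -1.28. Rrm2, a subunit of ribonucleotide reductase, fell from 5.08 ± 1.64 to 0.199 ± 0.062 FPKM (SD, n = 3; log2 fold change -2.30, SE 0.22, limma adjusted p = 0.0166). Cdk1, the mitotic kinase, fell from 3.61 ± 0.551 to 0.356 ± 0.326 FPKM (limma adjusted p = 0.0353), Ccna2, cyclin A2, from 3.08 ± 1.34 to 0.178 ± 0.103 (limma adjusted p = 0.0418), and Mki67, the proliferation marker Ki-67, from 2.41 ± 0.749 to 0.273 ± 0.12 (limma adjusted p = 0.0418). These 4 passed over all genes and 12 passed adjusted over the list alone. Stmn1, a microtubule regulator outside the list, fell from 17.8 ± 3.81 to 4.52 ± 1.36 FPKM (limma adjusted p = 0.0418). Cdkn3 (7.35 ± 2.39 and 0.15 ± 0.171 FPKM), Spc24 (3.78 ± 1.21 and 0.344 ± 0.18) and Ckap2 (2.199 ± 0.618 and 0.115 ± 0.13) also passed, with limma adjusted p of 0.0166, 0.0391 and 0.0404, and were singled out after their values were seen. The list ranked lower (camera adjusted p = 2.05e-13, and adjusted p = 0.227 with an estimated correlation). Fry gave an adjusted p of 0.0308. With a minimum mean of 5 FPKM only 1 member passed over the list alone. The median was -0.83 without control 1.

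Among the other genes past the threshold, Akr1c1, an aldo-keto reductase, fell from 10.8 ± 4.33 to 0.645 ± 0.578 FPKM (SD, n = 3; limma adjusted p = 0.0418) and RGD1564865 from 10.05 ± 4.78 to 0.54 ± 0.186 (limma adjusted p = 0.0404). Aldh1b1, a mitochondrial aldehyde dehydrogenase, fell 5.71-fold, from 12.02 ± 3.38 to 2.104 ± 0.337 FPKM (limma adjusted p = 0.0278), and Slc17a4, a transporter, 3.197-fold, from 12.9 ± 1.63 to 4.03 ± 0.847 FPKM (limma adjusted p = 0.0391). Akr1c1 belongs to a family of near-identical genes, so its value is uncertain. Another 5 of the 28 were new gene rows without a symbol. The 3 features that rose included Mthfd2, with 0.653 ± 0.287 FPKM in control and 9.15 ± 4.64 in TPN (limma adjusted p = 0.0422). The others were Fam129a, with 1.37 ± 0.593 FPKM in control and 6.61 ± 1.68 in TPN (limma adjusted p = 0.0418), and LOC100911319, with 0.515 ± 0.00588 FPKM in control and 2.41 ± 0.39 in TPN (limma adjusted p = 0.0418). These 3 lie under the mean of 5 FPKM set for named genes, and they were named after their values were seen. No higher gene met that rule. The 6 with the smallest unadjusted p did not pass, with limma adjusted p from 0.0781 to 0.114. In FPKM in control and then TPN they were Psat1 (2.32 ± 0.591 and 13.3 ± 6.503) of serine synthesis, LOC685203 (2.15 ± 0.839 and 8.04 ± 2.53), Asns (2.22 ± 1.86 and 24.1 ± 12.05), the asparagine synthetase, Angptl8 (23.8 ± 4.23 and 79.2 ± 28.4), Rps12 (59.1 ± 0.688 and 113 ± 10.8), a ribosomal protein, and Pcsk6 (11.2 ± 0.896 and 22.5 ± 4.1002). Ribosomal protein genes share reads with pseudogenes, so the value of Rps12 is uncertain.

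Of 20 measured genes of fatty acid and triglyceride synthesis, 17 had negative log2 fold changes (median -0.76), none passed over all genes, and 8 passed adjusted over the list alone, all lower. Acss2, the cytosolic acetyl-CoA synthetase, measured 40.2 ± 2.76 FPKM in control and 9.72 ± 4.73 in TPN (SD, n = 3), and Acacb, an acetyl-CoA carboxylase, 11.1 ± 3.1999 FPKM in control and 2.35 ± 1.37 in TPN. The desaturases Fads1 and Fads2 measured 261 ± 89.1 FPKM in control and 74.5 ± 37.1 in TPN, and 495 ± 126 FPKM in control and 109 ± 67.1 in TPN, and Fasn, the fatty acid synthase, 29.9 ± 7.95 FPKM in control and 14.5 ± 6.199 in TPN. Srebf1, a transcription factor of this pathway, measured 23.98 ± 11.3 FPKM in control and 31.6 ± 18.2 in TPN (log2 fold change 0.32, SE 0.52, limma adjusted p = 0.869). The list ranked lower (camera adjusted p = 1.24e-06, and adjusted p = 0.449 with an estimated correlation). Fatty acid oxidation and PPAR-alpha targets did not rank apart (camera adjusted p = 0.725, with a median of -0.036, a mean of 0.12 and a test direction up). In that list 13 of 29 members were positive and 1 passed over the list alone. Cpt1a, which brings fatty acids into mitochondria, measured 81.8 ± 10.8 FPKM in control and 103 ± 27.01 in TPN (limma adjusted p = 0.698), and Fgf21, a hormone made by liver, 2.71 ± 0.935 FPKM in control and 63.6 ± 78.1 in TPN (limma adjusted p = 0.382), with 33.6, 152 and 5.03 FPKM in the TPN rats. Lipid droplet and lipoprotein genes did not rank apart either (camera adjusted p = 0.947, median 0.11, mean -0.044, test direction down), with 1 member higher and 2 lower over the list alone. Their median was 0.029 without control 3 and 0.061 without TPN 1, and the list passed camera in neither fit. The sterol efflux list, of 14 members with 7 positive, gave a camera adjusted p of 0.313, and 1 member, Abcg8, passed over the list alone. Abcg8 measured 5.28 ± 1.83 FPKM in control and 1.096 ± 1.003 in TPN and its partner in sterol export Abcg5 14.9 ± 4.02 FPKM in control and 6.85 ± 4.33 in TPN (limma adjusted p = 0.195 and 0.443 over all genes).

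Of 11 measured genes of bile acid and bilirubin transport 10 had negative log2 fold changes (median -0.70), none passed over all genes and 4 passed adjusted over the list alone. These 4 were Abcc3 (3.304 ± 0.384 and 1.03 ± 0.402 FPKM in control and TPN, SD, n = 3), Slco1b2, an uptake carrier (248 ± 66.6 and 82.9 ± 20.9), Abcc2, which exports conjugated bilirubin (117 ± 45.3 and 44.7 ± 0.786), and Abcb11, the bile salt export pump (170.2 ± 10.2 and 109 ± 28.1). Slc10a1, the sodium-dependent bile acid importer, measured 307 ± 69.7 FPKM in control and 202 ± 92.04 in TPN (limma adjusted p = 0.559). The transport list ranked lower (camera adjusted p = 5.52e-05, and adjusted p = 0.368 with an estimated correlation). In bile acid synthesis 12 of 14 members were negative (median -0.48) and none passed, a count that includes Cyp7a1, the rate-limiting enzyme. Cyp7a1 measured 38.8 ± 21.4 FPKM in control and 40.05 ± 43.7 in TPN. Its log2 fold change was -0.34 (SE 0.83, limma adjusted p = 0.924), so it was lower on the log scale while its mean FPKM was slightly higher. Cyp8b1 measured 101 ± 31.5 FPKM in control and 52.4 ± 64.3 in TPN. Akr1c14 measured 665 ± 92.3 FPKM in control and 354 ± 135 in TPN. Amacr measured 223 ± 20.4 FPKM in control and 156 ± 17.4 in TPN and Hsd3b7 55.8 ± 11.4 FPKM in control and 38.8 ± 8.47 in TPN. That list ranked lower too (camera adjusted p = 0.0181, and adjusted p = 0.449 with an estimated correlation), and lost its call without control 2, TPN 1 or TPN 2 and after quantile normalisation. The median was -0.11 without TPN 1 and -0.72 without TPN 3. Bile acid sensing receptors did not rank apart (camera adjusted p = 0.185, 8 of 9 negative), and Nr0b2, the repressor SHP, measured 19.7 ± 3.49 FPKM in control and 16.5 ± 5.95 in TPN (limma adjusted p = 0.746).

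All 21 measured genes of the endoplasmic reticulum stress and amino acid response list had positive log2 fold changes (median 0.56), and 6 were higher in TPN without overlap. None passed over all genes and 1, Asns, passed over the list alone. The values were 2.598 ± 0.92 FPKM in control and 10.7 ± 9.56 in TPN for Trib3, 4.05 ± 0.518 FPKM in control and 7.48 ± 2.82 in TPN for Ddit3 and 65.7 ± 17.5 FPKM in control and 95.7 ± 6.84 in TPN for Atf4, a transcription factor of the amino acid response (SD, n = 3). The list ranked higher (camera adjusted p = 2.39e-07, and adjusted p = 0.21 with an estimated correlation). Fry gave an adjusted p of 0.0365. Of 28 genes of amino acid catabolism and the urea cycle 25 were negative (median -0.59), and 1, Bhmt, a betaine-homocysteine methyltransferase, passed over the list alone (715 ± 263 FPKM in control and 168 ± 82.5 in TPN). Cth measured 221 ± 127 FPKM in control and 72.1 ± 15.6 in TPN. Hal measured 51.2 ± 11.7 FPKM in control and 23.8 ± 10.3 in TPN and Oat 138 ± 75.7 FPKM in control and 33.7 ± 13.4 in TPN. This list ranked lower (camera adjusted p = 2.56e-05, and adjusted p = 0.449 with an estimated correlation). The median was -0.25 without TPN 1. Gluconeogenesis did not rank apart (camera adjusted p = 0.154, 8 of 13 positive), and Pck1, its rate-controlling enzyme, measured 384 ± 180.2 FPKM in control and 672 ± 112 in TPN (limma adjusted p = 0.434). Glycolysis gave a camera adjusted p of 0.793 with 8 of 18 positive. The growth hormone and insulin-like growth factor axis gave a camera adjusted p of 0.141 with 9 of 13 negative. In it Igf1 measured 402 ± 97.3 FPKM in control and 189 ± 48.6 in TPN (limma adjusted p = 0.229) and Igfbp1 225 ± 107 FPKM in control and 204 ± 99.5 in TPN (limma adjusted p = 0.938).

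**Figure D2:**
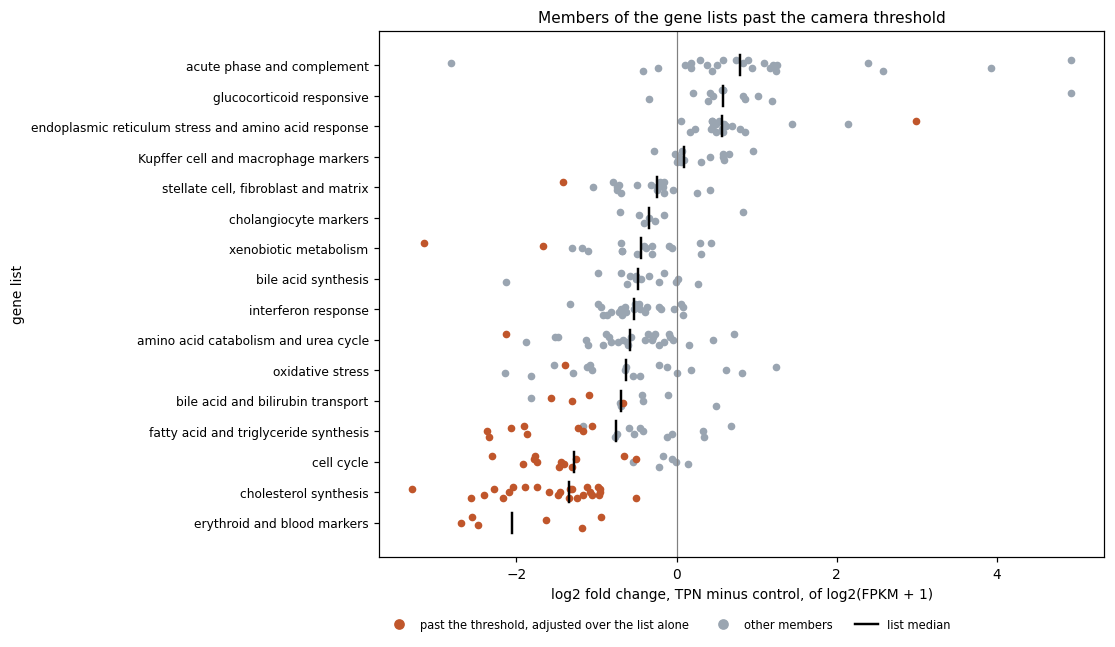
Log2 fold change (TPN minus control, of log2(FPKM + 1), horizontal axis) of each measured member of the 16 gene lists past the camera threshold with a preset correlation. Each point is 1 gene, orange where it passed adjusted over its list alone, and black bars are list medians. All 25 cholesterol synthesis genes and all 6 erythroid genes lie below 0, and all 21 genes of the endoplasmic reticulum stress and amino acid response list lie above 0.

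Acute-phase and complement genes were positive in 21 of 24 members (median 0.79), which are rows of the table and hold Cfb in 2 rows, and none passed over all genes or over the list alone. The members ran from a log2 fold change of -2.81 to 4.93, with 2 higher and 1 lower in TPN without overlap. The rats within each group differed widely. Lcn2, an iron-binding protein of the acute-phase response, measured 9127, 172 and 77.2 FPKM in TPN 1, 2 and 3 and 3.68, 112 and 7.29 in control 1, 2 and 3. A2m measured 1696 FPKM in TPN 1 and 84.1 in control 2, against 1.202 and 6.69 in the other controls. Lbp measured 123 ± 146 FPKM in control and 412 ± 166 in TPN (SD, n = 3). Cfb measured 21.3 ± 3.18 FPKM in control and 36.6 ± 7.71 in TPN in the row with the smaller p, and 662 ± 137 FPKM in control and 853 ± 73.2 in TPN in the other. Fgg measured 4125 ± 2580.2 FPKM in control and 9001 ± 4212 in TPN and Fga 2903 ± 1834 FPKM in control and 6149.5 ± 2845 in TPN. The first principal component held 42.4% of the variance, and 7 of the 24 acute-phase members were among its 50 largest loadings toward TPN 1. The list ranked higher (camera adjusted p = 2.56e-05, and adjusted p = 0.449 with an estimated correlation). The median was 1.18 without control 2. Glucocorticoid responsive genes were positive in 12 of 13 members (median 0.58), none passed, and they ranked higher (camera adjusted p = 0.00775, and adjusted p = 0.449 with an estimated correlation). That call was lost without control 1 or TPN 2. The median was 0.27 without control 1, 0.90 without TPN 1 and 0.35 without TPN 2. Lcn2 is also a member of the glucocorticoid list and has its largest log2 fold change (4.93), so this list is not independent of the acute-phase list. Sult1e1 measured 282 ± 39.2 FPKM in control and 424 ± 79.1 in TPN. Zbtb16 measured 1.99 ± 0.8 FPKM in control and 6.26 ± 5.61 in TPN and Tat 168 ± 79.3 FPKM in control and 329.7 ± 218 in TPN. Kupffer cell and macrophage markers were positive in 12 of 15 members (median 0.089), none passed, and they ranked higher (camera adjusted p = 0.0344, and adjusted p = 0.65 with an estimated correlation). That call was lost without control 1, control 3, TPN 1 or TPN 2, and after median-ratio scaling or quantile normalisation. The median was 0.14 without control 1, 0.42 without control 2, 0.0061 without control 3, 0.059 without TPN 1, 0.26 without TPN 2 and 0.32 without TPN 3. Marco measured 67.9 ± 5.76 FPKM in control and 136 ± 37.2 in TPN. Cd68 measured 17.5 ± 4.89 FPKM in control and 27.6 ± 4.61 in TPN, Cd163 19.4 ± 5.85 FPKM in control and 28.5 ± 1.86 in TPN and Cd5l 121 ± 23.9 FPKM in control and 186 ± 58.5 in TPN.

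**Figure D3:**
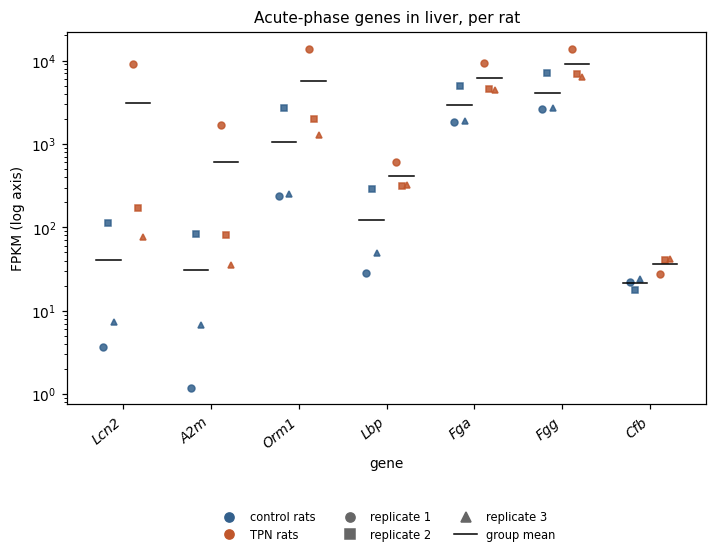
FPKM on a log axis of 7 acute-phase genes in the liver of 3 control and 3 TPN rats. Each point is 1 rat, its shape gives the replicate number and the horizontal lines are group means. Lcn2 runs from 3.68 to 112 FPKM among controls and from 77.2 to 9127 among TPN rats. Cfb is drawn from its row with the smaller p.

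Interferon response genes were negative in 20 of 23 members (median -0.53), none passed, and they ranked lower (camera adjusted p = 6.45e-06, and adjusted p = 0.449 with an estimated correlation). Rsad2 measured 1.93 ± 0.857 FPKM in control and 0.441 ± 0.14 in TPN. Psmb9 measured 24.03 ± 3.95 FPKM in control and 12.5 ± 4.77 in TPN, Ddx58 13.8 ± 1.83 FPKM in control and 9.25 ± 1.53 in TPN and Bst2 207 ± 42.6 FPKM in control and 131 ± 7.81 in TPN (SD, n = 3). Cytokines, chemokines and NF-kB targets did not rank apart (camera adjusted p = 0.51, 10 of 15 positive), with 1 member higher over the list alone. MHC class II genes did not either (camera adjusted p = 0.947, 5 of 9 positive), and Cd74 of that list measured 386 FPKM in control 2 against 65.5 and 61.3 in the other controls.

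Among markers of other cells that a piece of liver can hold, stellate cell, fibroblast and matrix genes were negative in 17 of 19 members (median -0.24), none passed over all genes and 1, Lrat, which makes retinyl esters in stellate cells, passed over the list alone (13.6 ± 2.0002 FPKM in control and 4.596 ± 1.69 in TPN, SD, n = 3). Col5a1 measured 6.76 ± 0.998 FPKM in control and 3.76 ± 1.17 in TPN. Mmp2 measured 6.25 ± 1.58 FPKM in control and 3.31 ± 0.825 in TPN and Col3a1 109 ± 26.8 FPKM in control and 63.96 ± 11.7 in TPN. This list ranked lower (camera adjusted p = 3.95e-04, and adjusted p = 0.449 with an estimated correlation). That call was lost without control 2 or TPN 3 and with sample weights. The median was -0.13 without control 2, -0.51 without control 3 and -0.46 without TPN 2. Acta2, which marks activated stellate cells, measured 4.12 ± 1.98 FPKM in control and 3.52 ± 1.62 in TPN (limma adjusted p = 0.922) and Col1a1 9.48 ± 5.55 FPKM in control and 3.88 ± 2.08 in TPN (limma adjusted p = 0.443). Cholangiocyte markers were negative in 6 of 7 members (median -0.35), none passed, and they ranked lower (camera adjusted p = 0.0385, and adjusted p = 0.449 with an estimated correlation). That call was lost without control 1 or any of the 3 TPN rats, with a mean of at least 5 FPKM and with sample weights. Epcam measured 8.22 ± 2.06 FPKM in control and 4.59 ± 0.653 in TPN. Krt19 measured 2.33 ± 0.722 FPKM in control and 1.36 ± 0.153 in TPN, Anxa4 14.6 ± 2.54 FPKM in control and 11.3 ± 2.76 in TPN and Aqp1 3.72 ± 1.04 FPKM in control and 2.86 ± 0.432 in TPN. Endothelial markers did not rank apart (camera adjusted p = 0.949, 9 of 14 negative). Lists with under 5 measured members were not tested as lists. Of T and NK cell markers 3 were measured and 1 was lower over the list alone, of pancreas markers 2 were measured and 1 was lower, and none passed among 2 B and plasma cell, 2 neutrophil, 3 adipocyte and 1 intestine and stomach markers, while 0 muscle markers were measured.

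Xenobiotic metabolism genes were negative in 15 of 18 members (median -0.45), and Cyp2c7 (1724 ± 616 FPKM in control and 228 ± 141 in TPN, SD, n = 3) and Cyp2c23 (425 ± 99.9 FPKM in control and 140.3 ± 60.04 in TPN) were the 2 lower over the list alone. Cyp1a2 measured 418 ± 68.5 FPKM in control and 189 ± 112 in TPN and Cyp2c11 87.7 ± 37.8 FPKM in control and 43.1 ± 29.2 in TPN. Cyp2c genes are a family of similar sequences that can share reads, so their values are uncertain. The list ranked lower (camera adjusted p = 0.00698, and adjusted p = 0.449 with an estimated correlation). That call was lost without control 2 or TPN 1 and with sample weights. The median was -0.25 without control 2, -0.17 without TPN 1 and -0.77 without TPN 3. Oxidative stress genes (NRF2 targets) were negative in 14 of 19 members (median -0.64) and ranked lower (camera adjusted p = 0.00775, and adjusted p = 0.449 with an estimated correlation). That call was lost without a filter and with a mean of at least 0.1 FPKM. The median was -0.37 without TPN 1. Gpx1, a glutathione peroxidase, was the 1 member lower over the list alone (652 ± 253 FPKM in control and 236 ± 24.4 in TPN), while Nqo1 measured 18.7 ± 8.78 FPKM in control and 43.1 ± 7.999 in TPN, Sod1 651 ± 20.6 FPKM in control and 421 ± 83.3 in TPN and Gsta3 49.2 ± 21.8 FPKM in control and 14.8 ± 17.1 in TPN. Hepatocyte secreted proteins did not rank apart (camera adjusted p = 0.117), with 3 of 15 members lower over the list alone, and Alb, albumin, measured 42954 ± 9050.5 FPKM in control and 27621 ± 13519.6 in TPN (limma adjusted p = 0.597). The remaining lists gave camera adjusted p of 0.297 for sex-linked and sex-biased genes, 0.564 for the circadian clock, 0.382 for metal and iron handling, 0.209 for the mitochondrial respiratory chain and 0.74 for p53 targets and apoptosis. In the clock list Nr1d1, the repressor REV-ERB alpha, was the 1 member lower over the list alone (24.6 ± 7.83 FPKM in control and 8.18 ± 3.804 in TPN, without overlap, limma adjusted p = 0.173, and 0.0312 with the replicate number as a block). Over all 32 lists tested, 16 passed camera with a preset correlation, 4 higher and 12 lower. With an estimated correlation 0 passed camera, 4 had an unadjusted p under 0.05, and fry passed 4 lists, 3 lower and 1 higher.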

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

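The covariate fits and the joint removal of control 2 and TPN 1 were chosen after seeing the data. The count of 28 features (3 higher, 25 lower, all at least 2-fold) changed with most settings, and the cause was not tested unless named. It was 18 (2 higher, 16 lower) with a pseudocount of 0.1, 5 (0 higher, 5 lower) with 0.01, 6 (0 higher, 6 lower) with a mean of at least 5 FPKM, where fewer features are tested, 8 (0 higher, 8 lower) without trend or robust settings, 299 (95 higher, 204 lower) with sample weights, of which 176 were at least 2-fold, and 24 (2 higher, 22 lower) with TPM. It was 0 by limma without a filter, after median-ratio scaling and after quantile normalisation, where 1898, 1573 and 1591 had an unadjusted p under 0.05, and the smallest adjusted p were 0.113, 0.0571 and 0.0512. It was 1 (0 higher, 1 lower) with the acute-phase covariate, 44 (3 higher, 41 lower) with the clock covariate, 46 (3 higher, 43 lower) with Nr1d1 and Nr1d2 in the clock score, and 121 (44 higher, 77 lower) without control 2 and TPN 1, where 25 of the 28 were shared. Leaving out 1 rat gave 0 to 46 features, 0 to 11 higher, 0 to 35 lower and 0 to 46 at least 2-fold. With a mean of at least 0.1 FPKM or same symbols summed the count stayed within 1.5 times. Of the 28, Tm7sf2 passed in 12 of the 18 alternatives fixed beforehand, Rrm2, Dhcr7 and Aldh1b1 in 11, and Msmo1, Akr1c1 and Hba-a1 in 4.

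The lists past camera numbered 12 to 16 under every alternative of the gene fit and 16 on ranks, but 0 with an estimated correlation (4 at an unadjusted p under 0.05) and 4 by fry. Over the list alone, cholesterol synthesis had 20 to 25 lower members past the threshold under every alternative. Cell cycle had 9 to 15, except 19 without a filter and with a mean of at least 0.1 FPKM, where more members are measured, and 1 with a mean of at least 5 FPKM, where fewer are. Erythroid genes had 4 to 8, except 3 with a mean of at least 5 FPKM, where fewer are measured, and 4 to 6 when 1 rat was left out.

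The rats share replicate numbers, but over all genes the deviations of same-numbered rats correlated at -0.21, -0.14 and 0.32 for numbers 1, 2 and 3, and control 2 correlated best with TPN 1 (0.42). Over 16 clock genes, which are not independent and were chosen for this check after seeing their values, each rat correlated best with the rat of its own number, at 0.89, 0.69 and 0.85, against -0.78 to 0.10 for other pairs. Deviations from the mean of a group of 3 cancel out, so a high correlation in 1 pair forces lower ones in others. The contrast with the other pairs is thus partly built in. The match of the numbers is a hint from the data that same-numbered rats were sampled at similar times, and the labels used here do not say whether they were. The counts without the block and the splits of the samples take no account of it. With the replicate block 58 (6 higher, 52 lower) features passed, 58 of them at least 2-fold and 26 of them among the 28, and 15 lists.

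Of the values of single genes, 1736 kept their direction and side of the threshold over the alternatives, 229 lost and 48 gained a call, and 14 changed sign. For list medians the numbers were 612, 37, 11 and 40. Only a gene or list called in the main fit can lose a call, and most of the named genes were not called there. The 1736 thus holds many genes without a call in either fit and does not measure how stable the calls were. The cause of the changes of sign was not tested. With the acute-phase covariate they were bile acid sensing receptors (0.013), fatty acid oxidation and PPAR-alpha targets (0.18), glycolysis and glucose uptake (0.30), cytokines, chemokines and NF-kB targets (-0.19), MHC class II and antigen presentation (-1.29), Kupffer cell and macrophage markers (-0.18), sex-linked and sex-biased liver genes (0.045), circadian clock (0.33), metal and iron handling (-0.10), mitochondrial respiratory chain (0.18), Slc10a1 (0.0033), Anxa4 (0.0099). With sample weights they were growth hormone and insulin-like growth factor axis (0.14), hepatocyte secreted proteins (0.0079), Acta2 (0.26), Igfbp1 (0.37), Nr0b2 (0.082). Without control 2 and TPN 1 they were glycolysis and glucose uptake (0.10), endothelial markers (0.044), xenobiotic metabolism (0.041), circadian clock (0.12), Cyp7a1 (0.28). With the clock covariate it was sterol efflux and LXR targets (0.034), with TPM sterol efflux and LXR targets (0.014), with a mean of at least 5 FPKM sterol efflux and LXR targets (0.019), with quantile normalisation sterol efflux and LXR targets (0.015), fatty acid oxidation and PPAR-alpha targets (0.046), with a mean of at least 0.1 FPKM MHC class II and antigen presentation (-0.056) and without a filter MHC class II and antigen presentation (-0.041). Leaving out 1 rat gave ranges across 0 for MHC class II and antigen presentation (-0.33 to 0.47), p53 targets and apoptosis (-0.073 to 0.021), sex-linked and sex-biased liver genes (-0.39 to 0.011), sterol efflux and LXR targets (-0.17 to 0.082), endothelial markers (-0.22 to 0.10), Acta2 (-0.54 to 0.17), Cyp7a1 (-1.20 to 0.29), Igfbp1 (-0.57 to 0.33), Srebf1 (-0.093 to 0.78), circadian clock (-0.33 to 0.17), fatty acid oxidation and PPAR-alpha targets (-0.085 to 0.11), glycolysis and glucose uptake (-0.21 to 0.15), cytokines, chemokines and NF-kB targets (-0.041 to 0.25), mitochondrial respiratory chain (-0.33 to 0.0096), growth hormone and insulin-like growth factor axis (-0.43 to 0.14). Depth is unknown, so no limit from counting error can be given.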

Other observations

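Every test of an explanation here was chosen after the result was seen, except the splits of the samples, and the gene groups of the first paragraph were assembled after seeing the values. Of 11 measured enzymes of serine and one-carbon metabolism and amino acid transporters 9 had positive log2 fold changes in TPN (median 0.93), and 6 passed adjusted over the group alone, which is not independent evidence. Phgdh, the first enzyme of serine synthesis, measured 3.35 ± 1.396 FPKM in control and 23.2 ± 14.7 in TPN, Psph 5.004 ± 0.691 FPKM in control and 10.5 ± 2.397 in TPN and Slc3a2, a subunit of amino acid carriers, 28.5 ± 3.66 FPKM in control and 64.6 ± 28.7 in TPN (SD, n = 3), while Shmt2 measured 61.9 ± 12.6 FPKM in control and 69.2 ± 9.88 in TPN. Of 18 aminoacyl-tRNA synthetases 17 were positive (median 0.56) and 8 passed over the group alone, with 8.84 ± 0.808 FPKM in control and 17.4 ± 4.95 in TPN for Cars and 19.1 ± 4.24 FPKM in control and 40.1 ± 16.3 in TPN for Yars. None of the 18 passed over all genes. The p of the synthetases was 0.0312 by fry and 0.0751 by camera with an estimated correlation. Of 86 rows of cytosolic ribosomal protein genes, of which some share a symbol, 80 were positive (median 0.38) and 65 were higher without overlap, against 10% for both directions by chance. That rate is for single genes, and these genes can move together, so the 65 rows are not independent. Over all 11362 tested features 911 were higher without overlap. With rows of the same symbol summed 75 of 80 genes were positive. None of the 86 rows passed over the group alone by limma, the p of the group was 0.003 by fry and 0.0507 by camera with an estimated correlation, and its median stayed between 0.29 and 0.47 in all 22 alternatives, scalings included. Ribosomal protein genes share reads with pseudogenes. The other group, of 13 mitochondrially encoded genes, had 3 positive members (median -0.083), and its p was 0.583 by camera with a preset correlation and 0.795 by fry. Its direction depended on single rats, turning positive without TPN 1 (11 positive, median 0.17), without control 1 (10 positive, median 0.031), without control 2 and TPN 1 (10 positive, median 0.12) and with the acute-phase covariate (12 positive, median 0.28), and falling further without TPN 3 (0 positive, median -0.24).

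Clock genes differed between rats of a group. Dbp measured 69.003 FPKM in control 3 and 27.5 in TPN 3, against 6.499 and 6.46 in the other controls and 1.69 and 4.05 in the other TPN rats. Arntl, which peaks at the opposite phase, measured 2.23 and 1.42 in those rats and 10.9 and 7.07 in control 1 and TPN 1. Nr1d1 measured 19.3, 20.96 and 33.6 FPKM in control 1, 2 and 3 and 4.63, 7.72 and 12.2 in TPN 1, 2 and 3, so that it rose with the number in both groups and was lower in TPN at each number. Its limma adjusted p was 0.014 with the clock score, which leaves it out, as a covariate. Its fall was given no test of an explanation.

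The fall of the cholesterol synthesis genes kept 23 of its 25 members over the list alone with an acute-phase score as a covariate, 25 with a clock score as a covariate and 25 with Nr1d1 and Nr1d2 in that score. A factor per library moves all features alike, but the list median lay -1.35 from the median of all tested features, which was 0.0065. Their log2 fold changes had an SD of 0.42, which is a spread of single features and not of list medians. Under every alternative, the other scalings included, 20 to 25 members stayed lower over the list alone. These values argue against the acute-phase response and a scaling factor per library as the whole cause of the fall. The clock fits add no test of the time of sampling, but the groups covered like ranges of these scores. A change in Nr1d1 itself stays open. TPN itself stays open as untested, and so does whatever else may have differed between the groups. The labels used here do not say whether surgery or feeding by mouth differed.

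The fall of the erythroid and cell cycle genes could reflect less blood in the TPN livers. The 7 measured T, NK, B and neutrophil markers had a median log2 fold change of 0.014 (SD 0.56, -0.61 to 0.86) against -2.06 for erythroid genes, but only 2 are neutrophil markers and the others are also carried by leukocytes that live in the liver, so this cannot be told apart. Fewer erythroid precursor cells, which also carry cell cycle transcripts, may account for both. Of the 7 erythroid genes under the filter, only 1 had a control mean of at least 0.5 FPKM (Hemgn, 0.616 ± 0.184 and 0.059 ± 0.0594 FPKM), too few to tell fewer erythroid precursor cells from a change in other cells. Below that bound Gata1 and Kel were lower in TPN without overlap, and Epb42, Klf1, Rhag and Tspo2 overlapped between the groups. Tspo2 had the higher mean in TPN (0.432 ± 0.288 FPKM in control and 0.620 ± 0.313 in TPN).

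The spread of acute-phase genes set TPN 1 and control 2 apart. Without TPN 1 the median of the list was 0.68 against 0.79, but by camera with an estimated correlation the list had an unadjusted p of 0.209 with all rats and 0.424 without TPN 1. The difference between the groups is thus itself uncertain, and how far TPN 1 alone sets it cannot be told apart. A wrong group label was tested on lists with at least 50% of their members past the threshold over the list alone in a fit without that rat. The score of a list is its mean log2(FPKM + 1). In cholesterol synthesis, erythroid and cell cycle genes TPN 1 lay below the controls by 2.51, 5.16 and 1.55 times the width of their range, which argues against a wrong group label on it. Control 2 lay above the TPN rats by 2.48, 1.898 and 2.12 widths of their range in these lists, which counts against a wrong label too. In fatty acid synthesis it lay above them by only 0.0659 widths, under the bound of 1 set for every list, so for control 2 a wrong label and a spread within the group cannot be told apart by this test. On wider sets chosen without the rat, 58 of 90 list members and 55 of 100 features for control 2, and 63 of 80 and 66 of 100 for TPN 1, lay nearer the rest of their own group, shares that do not decide. No biological explanation for the spread within groups was tested.

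The 6 samples can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 28 features and the highest of the other splits 2, and for features at least 2-fold these were also 28 and 2. The real split gave 25 lower and 3 higher features, and the highest count in either direction among the others was 2. For members past the threshold over the list alone, the real split gave 25 in cholesterol synthesis, 12 in cell cycle and 6 in erythroid genes, and the highest of the others was 0 in each. A gap between the real groups widens the spread within every other split and so lowers its count of features or members. Only the rank of the real split among the 10 can thus be read, not the size of these contrasts. The lists past camera with a preset correlation were 16 in the real split, and the 9 other splits gave 4 to 16, so 2 of the 10 splits gave as many and the count of 16 lists does not separate the groups from other splits. The split of control 1, control 3 and TPN 3 against the rest had 1718 features at an unadjusted p under 0.05, above the 1300 of the real split.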
